A study of Homo sapiens with 4 samples.

How the data were processed

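Total RNA from cells labelled HepG2 and transfected with the control duplex (NC), the miR-214 mimic, siPVT1-1 or siPVT1-2 was amplified, labelled with the dye Cy5 and hybridised to OneArray Plus chips in 1 colour, per the labels' protocols. Each group held 1 array. No source used here says which strand the mimic carries or how long after transfection the RNA was taken. The software behind the deposited values is not given in the sources used here.

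The authors deposited linear intensities with background already subtracted, as the values themselves show: 131, 101, 129 and 74 of 28264 probes lay below 0 on the NC, mimic, siPVT1-1 and siPVT1-2 arrays. On each array at least 99.97% of values were whole multiples of 1 constant, within a tolerance of 0.02 of a unit; the constants were 0.8018, 1.0161, 1.0448 and 1.1738. The 75th percentiles of the deposited intensities were 4081, 3934, 3881 and 3839, and their distributions were not matched, so normalization between arrays was still needed. A constant per array cannot remove a curve of intensity between arrays, and the scale set by it can move the split of higher and lower genes.

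Deposited intensities were quantile-normalized with limma 3.58.1 in R 4.3.3, set to a floor of 64 and taken to log2. Of the deposited values, before normalization, 8.1, 9.5, 9.9 and 11.7% lay below this floor on the NC, mimic, siPVT1-1 and siPVT1-2 arrays. The floor itself was applied after quantile normalization, which gives all arrays a common distribution. Signal over background and the single array per group set the precision, and dim genes are the least certain. A ratio with a spot under the filter level on either array has an uncertain size. Probes were named from the platform annotation given, with symbols updated by Entrez identifier to the RefSeq gene table of GRCh38.p14; all 25893 identifiers matched. Of the probes, 25893 had 1 gene symbol, 0 had several and 2371 had none here. They covered 19090 genes. A gene was represented by its brightest probe by mean over the 4 arrays, and where a further probe of a named gene disagreed on direction or on the 2-fold rule, the text gives its value. Small differences within 2-fold are not listed. Genes were compared when their mean log2 level exceeded 9.72, the median of all probes, which left 10668. Of these, 2 at the floor on an array were neither ranked nor counted. No genome or transcript sequences were used, so no coordinates are given, and sites of miR-214 in transcripts and the level of PVT1 were not analysed here.

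The difference for a gene is the log2 level on one array minus that on another. With 1 array per group no test was used for the reported differences, and genes at least 2-fold apart were counted by this rule of size. The words higher and lower refer to it for single genes. For 25 gene lists, the median log2 difference of members above the level filter was placed among 10000 random lists of the same size matched on mean level, and a list was said to stand apart outside percentiles 2.5 to 97.5. This percentile describes these arrays and is no p-value. Of 530 list entries, 487 had a named probe. Of the 75 list medians against NC, 25 lay outside the random range. Gene lists, comparisons, the rule of size, the rule for named genes and most alternatives were fixed before the data were examined.

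Named genes were the 10 highest and 10 lowest for the mimic, the 10 of each direction by the smaller difference for both siRNAs, the 5 highest and 5 lowest between the siRNAs, the 5 each way shared by all 3 treated arrays by the smallest difference, and MYC. From each list up to 4 members with the largest absolute difference were eligible. Cell type markers whose single levels are given were picked from their lists after the values were seen.

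Because all differences from NC share 1 array, counts, correlations and covariances were set beside 100 simulated draws of unchanged arrays with a common control. Their noise was drawn from the siPVT1-1 minus siPVT1-2 differences divided by the root of 2. The counting procedure was tested on simulated data for the mimic comparison over 10658 genes. It called 96.0% of genes raised 3-fold, 10.0% of those raised 1.5-fold, 64.4% of those halved to 0.5 and 95.5% of those lowered to 0.333 of their level. Of 10444 unchanged genes it called 17, or 0.16%. The noise in this test was normal, with its spread at each level taken from the siPVT1-1 minus siPVT1-2 differences. These rates hold for that noise only. The real siRNA arrays were 2-fold apart at 53 of 10668 genes, and the mimic and NC arrays differed with a wider spread, so real error rates may be higher.

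The alternatives were the values as deposited, median centring, cyclic loess, no level filter, a filter at the 75th percentile, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, and limma with both siRNA arrays as 1 knockdown group. A floor of 1, comparisons without the NC array and the p53 list without SESN2 and GDF15 were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 computed the lists and simulations.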

Results

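Cells labelled HepG2, a human line from a liver tumour, were transfected with 1 of 4 small double-stranded RNAs. They were a negative control duplex without a human match (NC), a mimic of the microRNA miR-214, and a pair of small interfering RNAs against the long noncoding RNA PVT1 (siPVT1-1 and siPVT1-2). PVT1 lies beside the oncogene MYC on chromosome 8, and the series title sets PVT1 beside miR-214 in hepatocellular carcinoma. Each transfection was measured on 1 OneArray Plus expression array, so no difference between arrays has a replicate check and the differences are given without p-values. Each array carried 28264 probes. Their median deposited intensity was 926.9 on the NC array, 828.1 on the miR-214 mimic array, 835.9 on the siPVT1-1 array and 784.1 on the siPVT1-2 array. Comparisons covered 10668 genes above a fixed signal level, and a gene was counted as higher or lower when its normalized intensity differed at least 2-fold. The number of arrays limits the precision of every value. All differences from NC rest on 1 control array, so a shift seen on every treated array may stem from that array.

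On all 4 arrays the probes of basic cell machinery genes gave high signal and those of differentiated hepatocytes gave low signal; signal also depends on the probe, so these percentiles rank signals and not transcript amounts. The median cytosolic ribosomal protein gene stood at percentile 99.7 of all named genes by mean level, and the median oxidative phosphorylation gene at percentile 97.5. The median of 27 hepatocyte genes stood at percentile 27.7, with members between percentiles 7.2 and 63.5. Albumin (ALB) stood at percentile 13.2, alpha-fetoprotein (AFP) at 27.8, transthyretin (TTR) at 23.3, the fibrinogen chain gene FGB at 8.9 and apolipoprotein A1 (APOA1) at 53.1. Of the 27 hepatocyte genes, 22 lay under the level filter. No separate check of the cell line's identity was made. The low hepatocyte signals leave the label HepG2 in question, and it is used here only as the labels give it. The medians of marker lists for other cell types were 35.5 for blood cells, 36.7 for endothelium, 37.4 for fibroblasts and 34.8 for squamous and other epithelial lines. Among these markers, LUM (percentile 97.9), COL5A1 (93.9), DCN (91.0) and KRT7 (96.1) lay above percentile 90. Most of the fibroblast list was dim, with 4 of its 12 markers above the level filter. Its markers COL3A1 (3.0), POSTN (3.0), COL6A3 (6.4) and COL1A2 (13.4) were among the dim ones. The 5 hepatocyte genes above the filter had median log2 differences from NC of 0.21 on the mimic array, 0.07 on the siPVT1-1 array and -0.26 on the siPVT1-2 array, none of them outside the central 95% of random lists.

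**Figure D1:**
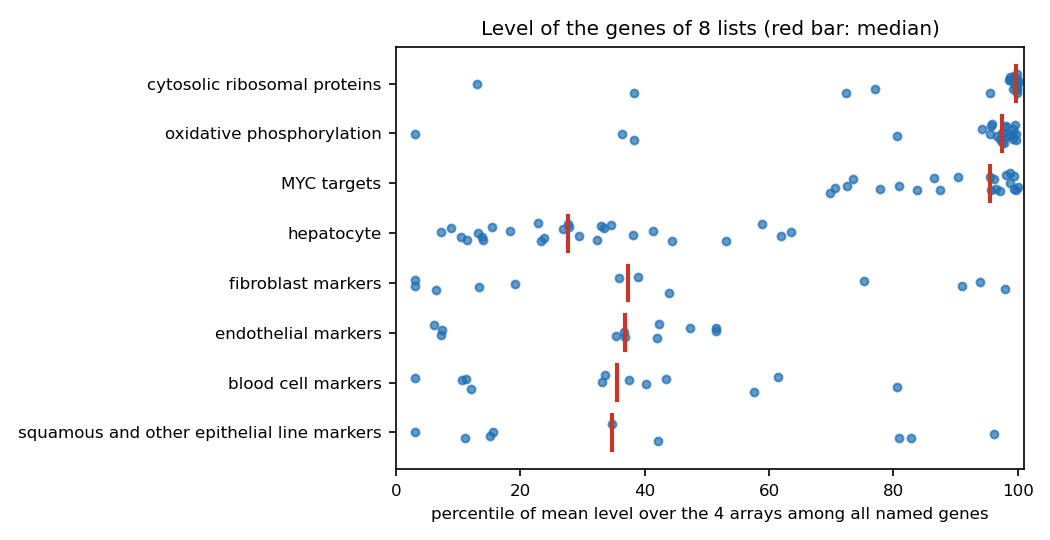
Level of the genes of 8 lists. Each point is 1 gene, placed on the horizontal axis by the percentile of its mean log2 intensity over the 4 arrays among all named genes, and the red bar is the list's median; the hepatocyte median lies at 27.7 and the ribosomal protein median at 99.7.

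The first comparison asked what the miR-214 mimic altered relative to the control duplex. Of 10668 genes, 208 were higher and 303 lower on the mimic array. The secreted WNT inhibitor DKK1 was 5.9-fold higher, the vasodilator peptide gene ADM 5.48-fold, the endothelin gene EDN2 5.34-fold, SPAG4 4.88-fold, KXD1 4.65-fold, BRI3BP 4.38-fold, the keratin gene KRT8 4.06-fold, FAM13A 3.99-fold and COXFA4L2 3.89-fold. The stress-induced cytokine GDF15 was 6.27-fold lower, NIBAN1 6.02-fold lower, DHRS2 5.53-fold lower and the receptor gene CMKLR2 6.97-fold lower, and these 4 were also lower on both siPVT1 arrays. STARD7, a lipid transfer protein gene, showed the highest ratio, 48.6-fold, but its log2 level was 8.18 on the NC array and 13.79 to 14.13 on the other arrays, so 1 control spot set this value. The NC levels of KRT8 (8.59), FAM13A (8.54), COXFA4L2 (8.43) and BRI3BP (9.3), and of MVK (9.43) and ANKRD37 (9.19) named later, also lay under the filter level of 9.72, so these ratios rest on a dim control spot too.

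Part of the genes that were lowest with the mimic were not lower with either siRNA. The bitter taste receptor gene TAS2R39 had a log2 difference from NC of -3.2 on the mimic array, against -0.46 and -0.37 on the siPVT1-1 and siPVT1-2 arrays. The transporter gene SLC22A24 (-3.07), the channel gene HCN4 (-2.69), LBH (-2.64) and the bile acid receptor gene GPBAR1 (-2.56) likewise differed by under 2-fold on both siPVT1 arrays. The chemokine receptor gene CCR6 (-2.84) was also lower with siPVT1-2 (-2.04) but not with siPVT1-1 (-0.32). CCR6, HCN4 and GPBAR1 each have further probes, which lay under the level filter and did not show the drop with the mimic. They gave 0.82 and 0.0 for CCR6 (-0.72 and 0.0 with siPVT1-2), 0.1 for HCN4 and 0.05 for GPBAR1; with probes averaged, the CCR6 difference was -0.67. On the mimic array TAS2R39 (8.16), SLC22A24 (7.68), HCN4 (8.76), LBH (9.36), GPBAR1 (8.99) and CCR6 (8.5) lay under the filter level, so the sizes of their differences are uncertain.

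Genes of the unfolded protein and amino acid stress response were lower as a group on the mimic array. Of 20 measured members, 10 were lower and 0 higher, and the list's median log2 difference of -0.9 lay below all 10000 random lists matched on level. The other 10 lay within 2-fold, 3 of them above 0. Not every member fell, as the following ones, named after their values were seen, show. With the mimic, siPVT1-1 and siPVT1-2, SDF2L1 stood at 0.44, 0.69 and 0.81. In that order HSP90B1 stood at 0.08, -0.23 and 0.12, and EDEM1 at -0.05, 0.1 and 0.03. Other unfolded protein genes were lower on all 3 arrays, such as XBP1 (-1.28, -1.37 and -1.15) and DNAJB9. The list joins unfolded protein and amino acid stress genes, so its median does not show that both kinds fell alike. The list included asparagine synthetase (ASNS, -1.94), the chaperone cofactor DNAJB9 (-1.96), the serine synthesis enzyme PSAT1 (-1.79) and the cystine transporter SLC7A11 (-1.56; a second probe near the floor, -0.26). Of 19 p53 target genes, 7 were lower and 0 higher, with a median of -0.87 that also lay below all random lists. The cell cycle inhibitor CDKN1A (-2.25) was lower by its second probe too (-1.35), and the DNA damage binding gene DDB2 (-1.42) and ZMAT3 (-1.27; second probe -0.35) were lower. Without SESN2 and GDF15, which also respond to amino acid stress, the p53 list's median was -0.71. This version was chosen after the data were seen. The members left in it were not screened for a link to stress, so it does not separate a p53 response from a stress response.

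Other lists lay above their random lists on the mimic array. An unusual NC array could also give these shifts. Cholesterol and fatty acid synthesis had a median of 0.6 over 18 genes, 3 of them higher: the sterol sensor partner INSIG1 (1.63), squalene epoxidase (SQLE, 1.35) and mevalonate kinase (MVK, 1.06). Glycolysis and hypoxia had a median of 0.46, with 6 of 20 genes higher, among them ADM (2.45), NDRG1 (1.66), ANKRD37 (1.47) and PFKFB4 (1.28). Mitosis genes had a median of 0.4 with 1 of 29 higher, cyclin A2 (CCNA2, 1.05; second probe 0.87), while the kinetochore motor gene CENPE stood at -0.97. DNA replication genes had a median of 0.19 and 0 of 29 past 2-fold, with CDC6 at -0.93. MYC targets had a median of 0.25, and 20 of 22 lay above 0, none by 2-fold; with the filter at the 75th percentile the list lay inside the random range. The metallothionein list, whose 5 measured genes include the zinc transporter gene SLC30A1, had a median of 0.57. Of these genes MT1X (1.0) was higher, but the list lay inside the random range without a level filter. The adhesion, matrix and motility list had a median of 0.23 with CCN1 (1.89) and KRT19 (1.27) higher, but it lay inside the random range with median centring, with values as deposited, with the filter at the 75th percentile and with probes averaged. Its direction did not turn under any of these.

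The literature miR-214 target list did not stand apart from random lists on the mimic array. Its 21 genes had a median of -0.09, at percentile 24.89 of random lists, and XBP1 (-1.28) was its 1 member past 2-fold. BCL2L2 stood at -0.83, CTNNB1 at -0.64 and E2F3 at 0.62. On the siPVT1 arrays XBP1 was lower to a like extent, -1.37 and -1.15, and the list's percentiles were 22.16 and 21.39; with the level filter at the 75th percentile, the siPVT1-2 median was -0.28 and lay outside the random range. Target sites in 3' untranslated regions were not analysed here. Medians inside the random range on the mimic array were also found for interferon response genes (-0.05), inflammatory and NF-kB genes (0.02, with IL1A at -1.31 and SAA1 at 1.13), apoptosis regulators (-0.14, with MCL1 at -1.16), WNT targets (0.13, with DKK1 past 2-fold), small RNA machinery (-0.01), Polycomb and DNA methylation genes (0.12), heat shock and immediate early genes (0.22), ribosomal proteins (0.03) and oxidative phosphorylation (-0.06, mean 0.02). The marker lists had medians of -0.02 for fibroblasts, 0.21 for endothelium, -0.13 for blood cells and -0.12 for squamous and other epithelial lines, all inside the random range. IL1A lay under the filter level on the mimic array (9.5), so the size of its difference is uncertain.

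The split between higher and lower genes depended on how arrays were brought to a common scale. With each array centred on its median, 351 genes were higher and 203 lower with the mimic, and the median of all compared genes then lay 0.108 above NC. Among 94 genes past 2-fold with a second probe above the filter, 79 had the same sign and 21 also passed 2-fold by that probe.

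**Figure D2:**
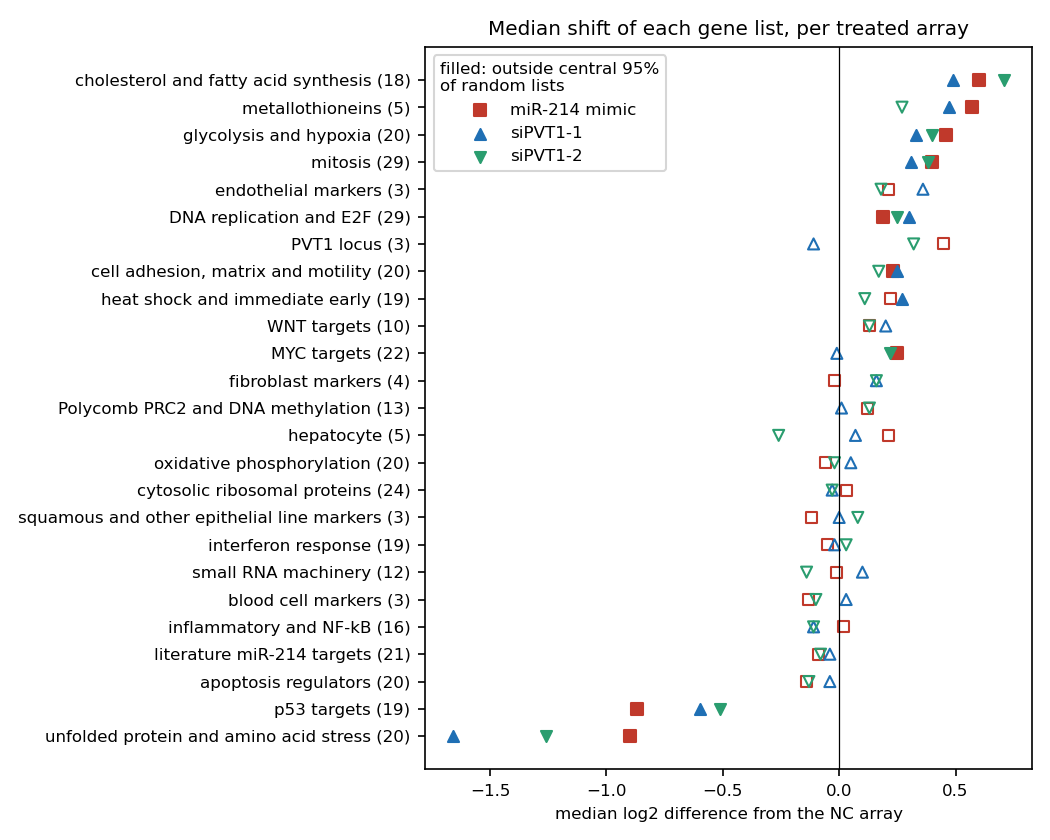
Median log2 difference from the NC array of each gene list on the 3 treated arrays, with the number of measured genes in brackets. Filled markers lie outside the central 95% of 10000 random lists matched on level; the stress list lies lowest, at -0.9 for the mimic, -1.66 for siPVT1-1 and -1.26 for siPVT1-2.

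The next comparison asked what loss of PVT1 altered, through a pair of duplexes against the same RNA. PVT1 itself was not analysed here because none of the probes was paired with that gene, so the arrays give no check of the knockdown. Its neighbour MYC had a log2 difference from NC of 0.13 with siPVT1-1, 0.32 with siPVT1-2 and 0.66 with the mimic. CYRIB, on the same chromosome, stood at -0.11, 0.56 and 0.45 in that order, and POU5F1B at -0.3, -0.11 and -0.09. A second POU5F1B probe, under the level filter, gave 1.17, 1.17 and 1.12. By their brightest probes none of these 3 genes passed 2-fold, and the locus list lay inside the random range on each array.

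Relative to NC, 133 genes were higher and 183 lower with siPVT1-1, and 142 were higher and 128 lower with siPVT1-2. Both siRNAs shared 74 higher and 95 lower genes. The lowest by the smaller of both differences were INHBE, an activin subunit gene, 11.07-fold lower with siPVT1-1 and 8.21-fold with siPVT1-2; GDF15, 9.38-fold and 6.06-fold; NIBAN1, 7.7-fold and 5.75-fold; and ASNS, 8.57-fold and 5.73-fold. BEX2, the neutral amino acid transporter gene SLC1A4, the growth factor binding protein gene IGFBP1, SLC7A11, DNAJB9 and C2orf78 were lower by 4.27-fold or more with each siRNA. On the siRNA arrays INHBE (9.13 and 9.56) and SLC1A4 (9.48 and 9.6) lay under the filter level, as did IGFBP1 with siPVT1-1 (9.71) and C2orf78 with siPVT1-2 (8.46), so the sizes of these ratios are uncertain. A second SLC7A11 probe, near the floor on every array, gave -0.26 with each siRNA. STARD7 again had the highest ratio, through its 1 low control spot. The ubiquitin ligase gene TRIM31 was 5.82-fold and 5.22-fold higher, KXD1 4.51-fold and 4.3-fold, EDN2 5.9-fold and 4.07-fold, FGFBP1 3.91-fold with each, DKK1 3.8-fold and 5.85-fold, EDN1 3.68-fold and 4.07-fold, KRT8 3.69-fold and 3.63-fold, COXFA4L2 3.58-fold and 3.76-fold, and NDRG1 3.49-fold and 3.7-fold. The NC levels of TRIM31 (9.35) and of DNMT3B (8.96), named later, like those of KRT8 and COXFA4L2, lay under the filter level.

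The stress response list was lower with both siRNAs. With siPVT1-1 its median was -1.66 and 13 of 20 genes were lower, and with siPVT1-2 the median was -1.26 and 12 of 20 were lower. No member was higher with either, and both medians lay below all 10000 random lists. Besides ASNS (-3.1 and -2.52), the serine synthesis enzyme PHGDH (-1.94 and -1.95) and SLC7A11 (-2.12 and -2.16) were lower, and with siPVT1-1 the glutathione-degrading enzyme CHAC1 (-3.67, at a dim level of 8.48) and the transcription factor DDIT3 (-2.36) were among the lowest. The p53 target list had medians of -0.6 and -0.51 with 5 of 19 genes lower for each siRNA, again below all random lists. CDKN1A (-1.81 and -2.14), SESN2 (-2.43 and -1.66) and GADD45A (-2.0 and -1.2) were among them. Without SESN2 and GDF15 the medians were -0.39 and -0.5, still outside the central 95% of random lists. As with the mimic, this does not separate a p53 response from a stress response.

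Sterol, glycolytic and cell cycle genes lay above their random lists with both siRNAs. Here too an unusual NC array could give the same shifts. Cholesterol and fatty acid synthesis had medians of 0.49 and 0.71 over 18 genes, with INSIG1 (1.56 and 1.58) and farnesyl diphosphate synthase (FDPS, 0.98 and 1.16; second probe 0.49 and 0.48) as examples. Fatty acid synthase (FASN) stood at 1.19 and 0.88. Glycolysis and hypoxia had medians of 0.33 and 0.4, with NDRG1 (1.8 and 1.89) and the glycolytic regulator PFKFB4 (1.91 and 1.36) higher, while the angiogenic factor gene VEGFA was lower (-1.52 and -1.17; second probe -0.94 and -0.51). Mitosis genes had medians of 0.31 and 0.38, and DNA replication genes 0.3 and 0.25, with 0 of 29 past 2-fold in each. BIRC5 (0.83 and 0.8) and MCM5 (0.83 and 0.77) were examples. Below 0 were 8 and 6 of the mitosis genes and 4 and 3 of the DNA replication genes, among them CDC6 (-0.73 and -0.64).

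Some lists lay outside their random lists with 1 of the siRNAs and inside with the other, while their siPVT1-1 minus siPVT1-2 medians lay inside. MYC targets had a median of -0.01 (mean 0.06) with siPVT1-1 and 0.22 with siPVT1-2, and the second value lay outside. Metallothioneins (0.47 and 0.27), adhesion, matrix and motility genes (0.25 and 0.17) and heat shock and immediate early genes (0.27 and 0.11) lay outside with siPVT1-1. Metallothioneins and adhesion genes lost this without a level filter and the heat shock list with median centring or values as deposited; adhesion genes lost it also with the filter at the 75th percentile, as did metallothioneins. The adhesion genes CCN1 (1.17 and 1.96) and KRT19 (1.13 and 1.64) passed 2-fold with both. Medians inside the random range were found for interferon response (-0.02 and 0.03), inflammatory and NF-kB genes (-0.11 and -0.11, with IL1A at -1.39 and -1.15), apoptosis regulators (-0.04 and -0.13), WNT targets (0.2 and 0.13), small RNA machinery (0.1 and -0.14, with a mean of -0.03 for siPVT1-1), Polycomb and DNA methylation genes (0.01 and 0.13, with the methyltransferase gene DNMT3B at 1.27 and 1.47), ribosomal proteins (-0.03 and -0.03) and oxidative phosphorylation (0.05 and -0.02). The marker lists, at 0.16 and 0.16 for fibroblasts, 0.36 and 0.18 for endothelium, 0.03 and -0.1 for blood cells and 0.00 and 0.08 for squamous and other epithelial lines, also lay inside it. IL1A lay under the filter level on both siRNA arrays (9.43 and 9.66), so the sizes of its differences are uncertain.

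Both siRNA comparisons share the NC array. In 100 simulated sets of unchanged arrays that share their control, 11.12 genes were higher and 11.82 lower on average in both, against the 74 and 95 observed; independent lists of the observed sizes would share 1.77 and 2.2. Across genes the differences of both siRNAs correlated with Pearson's r of 0.773 against a simulated 0.499, and their covariance was 0.141 against 0.042; genes are not independent replicates. Part of the excess may come from the shared control array, which cannot be split. With median centring the shared genes numbered 122 higher and 62 lower, those of siPVT1-1 184 and 146 and those of siPVT1-2 277 and 78; as deposited, they were 52 and 112, 94 and 215, and 95 and 161.

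**Figure D3:**
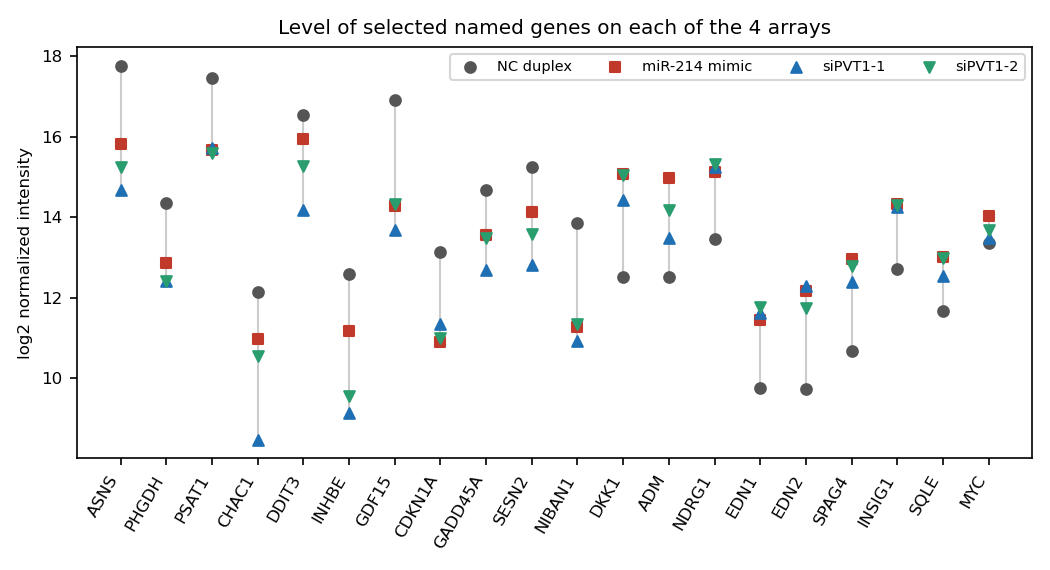
Log2 normalized intensity of selected named genes on each of the 4 arrays, 1 marker per array and no error bars because each transfection has 1 array. GDF15 lies at 16.93 on the NC array and at 13.7 to 14.33 on the treated arrays.

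The siRNAs differed from each other at fewer genes than either did from NC. Between their arrays 10 genes were higher and 43 lower with siPVT1-1 than with siPVT1-2, and the standard deviation of all log2 differences was 0.288, against 0.428 and 0.427 for each siRNA against NC. The lowest with siPVT1-1 relative to siPVT1-2 were the xanthine dehydrogenase gene XDH (-2.99), ZNF532 (-2.77), the muscle transcription factor gene MYOG (-2.56), C6orf15 (-2.51) and the milk fat globule protein gene MFGE8 (-2.17). The highest were C2orf78 (2.29), the small nuclear RNA RN7SK (2.04), CCR6 (1.72), LGI3 (1.58) and NEGR1 (1.28). A second XDH probe, also above the filter, gave 0.19 in place of -2.99. A second ZNF532 probe, under the filter, gave -0.38 in place of -2.77, so each value rests on 1 probe. With probes averaged CCR6 (0.68) and NEGR1 (0.64) fell short of 2-fold; the second NEGR1 probe lay at the floor and gave 0.0. XDH (8.93), MYOG (8.78), C6orf15 (8.74) and MFGE8 (9.46) lay under the filter level on the siPVT1-1 array, and C2orf78 (8.46), CCR6 (9.3), LGI3 (9.16) and NEGR1 (9.18) on the siPVT1-2 array.

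As a group, the stress response list was lower with siPVT1-1 than with siPVT1-2, by a median of -0.29 that lay below all random lists. CHAC1 (-2.08) was the lowest of its members. The cholesterol and fatty acid synthesis list had a median of -0.17 at percentile 0.78 of random lists, and the 5 measured hepatocyte genes had 0.29 at percentile 98.48. The p53 (0.01), mitosis (-0.01) and DNA replication (0.0) lists lay inside the random range.

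The last comparison set the miR-214 mimic beside the siRNAs. All 3 treated arrays shared 55 higher and 65 lower genes. By definition these are the genes at which the single NC array stood at least 2-fold apart from every other array. A response common to the treatments and an unusual control array therefore cannot be told apart for this set. The same holds for the shared shifts of the stress, p53, cholesterol, glycolysis, mitosis and DNA replication lists. Each lay outside the random range on the same side of NC on all 3 treated arrays. By the smallest of the 3 differences, the highest were STARD7, KXD1, EDN2, DKK1 and KRT8, and the lowest were GDF15, NIBAN1, BEX2, C2orf78 and DHRS2. BEX2 was 5.15-fold lower with the mimic, 5.28-fold with siPVT1-1 and 5.59-fold with siPVT1-2. DHRS2 was 5.53-fold, 5.81-fold and 3.94-fold lower in the same order. Of the 20 stress response genes, 10 were lower on all 3 arrays. The opposite pattern, with the mimic on one side and both siRNAs on the other, was met by 1 gene, the olfactory receptor gene OR51Q1 (-1.24 with the mimic, 1.14 and 1.03 with the siRNAs), named after its values were seen. It has 1 probe, which lay under the filter level on the mimic array (9.38), so the size of that difference is uncertain.

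Simulated unchanged arrays with a shared control gave 9.76 higher and 10.39 lower genes on all 3 arrays on average, and independent lists would share 0.03 and 0.06. The mimic differences and the mean siRNA differences correlated across genes with Pearson's r of 0.684 (simulated 0.577) and Spearman's rho of 0.661 (simulated 0.549). Taken one siRNA at a time, the mimic's correlation with siPVT1-1 was close to the simulated one (r of 0.538 against 0.5, rho of 0.481 against 0.48), and that with siPVT1-2 was higher (r of 0.75 against 0.499, rho of 0.753 against 0.48). The covariance with the siRNA mean was 0.135 against a simulated 0.042, a difference of 0.093. The mimic's covariance was 0.157 with siPVT1-2 and 0.113 with siPVT1-1, each against a simulated 0.042. The simulation takes its noise from the siRNA arrays alone, and part of the excess may come from the shared control. With median centring, 78 genes were higher and 41 lower on all 3 arrays.

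Compared directly, without the NC array, 51 genes were higher and 144 lower on the mimic array than on the mean of both siRNA arrays. Taken singly, siPVT1-1 differed from the mimic at 322 genes, 174 higher and 148 lower, and siPVT1-2 at 178 genes, 150 higher and 28 lower. The standard deviations of these differences were 0.445 and 0.33. These comparisons were added after the data were seen. The stress response list had a median of 0.49 in it, above all random lists, so it was less low with the mimic than with the siRNAs. The medians of MYC targets (0.23, percentile 99.95) and mitosis genes (0.13, percentile 98.37) also lay above the random range, with 0 members past 2-fold in either list. For siPVT1-1 minus the mimic alone, the mitosis median of -0.12 lay inside the random range. For siPVT1-2 minus the mimic alone, it was -0.1 and lay just outside, at percentile 2.48. MYC targets lay below the random range in both, at -0.29 for siPVT1-1 and -0.13 for siPVT1-2. For siPVT1-2 minus the mimic alone, DNA replication genes (0.18, percentile 99.82) lay above the random range and the measured hepatocyte genes (-0.33, percentile 1.04) below it. For the mimic minus the siRNA mean, the DNA replication median (-0.07) was inside the range. The p53 list (-0.07), the cholesterol list (0.06), the glycolysis and hypoxia list (-0.0) and the literature miR-214 targets (-0.03) lay inside the random range.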

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

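All tests in this part were chosen after the results were seen.

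On the siPVT1-1 and siPVT1-2 arrays 3 genes passed 2-fold against NC in opposite directions, and this difference between the siRNAs was not tested. XDH was lower with siPVT1-1 (-1.72) and higher with siPVT1-2 (1.27), a difference of -2.99 that its second probe did not show. MYOG stood at -1.37 and 1.19, a difference of -2.56. C6orf15 stood at -1.29 and 1.22, a difference of -2.51. Among 1003 probes above the level filter that carry no gene name here and entered no comparison, 2 were at least 2-fold above the control on all 3 treated arrays and 7 at least 2-fold below it.

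Hepatocyte genes were dim on all 4 arrays, with a median at percentile 27.7. Wrong pairing of probes with genes across the array is argued against by the ribosomal protein genes, whose median stood at percentile 99.7. Failed hepatocyte probes stay open: of the ribosomal and oxidative phosphorylation genes 5 of 49 (10.2%, 95% Wilson interval 4.4 to 21.8) lay under the level filter, against 22 of 27 hepatocyte genes (81.5%, 63.3 to 91.8), but the former are abundant transcripts and their probes say nothing of the hepatocyte probes. The bound set for this test was therefore wrong. Whether the cells lacked the hepatocyte programme stays open, and with it whether the label HepG2 is right. The dim hepatocyte signals bear on the label but cannot settle it, because signal also depends on the probe. The hepatocyte median lay at -7.8 percentile points relative to the blood cell markers, but 3 of those 12 markers lay above the level filter (CD3D at percentile 80.5), so their signals do not mark absence of expression. The CD3D value rests on 1 probe, since its second probe lay at the floor on all 4 arrays.

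Stress response genes were lower on all 3 treated arrays. Normalization between arrays as the cause is argued against by the weakest list median over 4 normalizations and 3 arrays, -0.59. A response common to the 3 transfections and a high stress state of the NC culture cannot be told apart for the 10 genes lower on all 3 arrays, because there is 1 control array. An effect shared by miR-214 and loss of PVT1 stays among the open explanations, untested.

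On the mimic array alone, 88 genes were lower by 2-fold than on each of the other 3 arrays and 3 were higher. The NC array stood alone in the same way at 55 lower and 65 higher genes, more in total, against 16 lower and 2 higher for siPVT1-1 and 1 lower and 7 higher for siPVT1-2. Those NC genes are the same 55 higher and 65 lower genes that all 3 treated arrays shared. Of the 88, 7 (8.0%) were olfactory or taste receptor genes, which made up 1.05% of all genes compared. Loss of signal at single probes may explain part of this: the second probes had a median difference of -0.09, but only 6 of the 88 genes have a second probe above the filter, while in the 18 such genes lower with both siRNAs the brightest probe gave -1.35 and the second -1.28. The sets were not matched on level: the 88 genes had a median log2 level of 10.82, and the 95 lower with both siRNAs one of 11.88. Repression by miR-214 also stays open, since untranslated regions were not analysed here and the literature target list lay at percentile 40.01 of random lists for the mimic minus the siRNA mean. Neither explanation is decided by these values.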

How the results depend on the processing

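The floor of 1, the comparisons without NC and the shorter p53 list were chosen after the data were seen; the other settings were planned. No list median that lay outside the random range against NC, and none of the 50 values of genes named by rank, changed sign under a setting that kept NC as reference; list members named singly were not followed through the settings. Of the list medians recomputed under other settings, 416 stayed on their side of the random range, 10 came to lie outside it and 12 came to lie inside; of named gene values 247 stayed past 2-fold and 3 did not. The correlation between mimic and siRNA differences ranged from 0.638 to 0.727. Counts in this paragraph are for the mimic, siPVT1-1, siPVT1-2, both siRNAs, and siPVT1-1 against siPVT1-2. Without a level filter they were 889, 599, 564, 283 and 203, with 2 genes opposite between mimic and siRNAs. With the filter at the 75th percentile they were 230, 148, 123, 82 and 10, with 63 genes on all 3 arrays and 0 opposite; fewer genes were compared. At 1.5-fold they were 2014, 1405, 1416, 783 and 354, with 539 on all 3 arrays and 10 opposite. At 3-fold they were 83, 73, 59, 41 and 21, with 24 on all 3 arrays and 0 opposite. As deposited, 0 genes were opposite; the cause was not tested. Without NC, 195 genes separated the mimic from the siRNA mean and 178 separated siPVT1-2 and 322 siPVT1-1 from the mimic, and 10 of 75 list medians lay outside the random range in place of 25; another reference array was used. By limma with 1 residual degree of freedom, which assumes that the lone arrays vary like the siRNA arrays, 475 genes had an adjusted p under 0.05 for the siRNAs and 711 for the mimic. The prior degrees of freedom of this limma fit were infinite, so its variance was pooled over genes and not estimated for each gene. That variance rests on the difference between different siRNA duplexes, not on replicates. The smallest absolute log2 differences called were 0.81 for the siRNAs and 0.9 for the mimic. The limma counts are therefore read as counts by size and not as significance. Sites of miR-214 and the PVT1 level, with all their alternatives, were not run because the sequences and a named PVT1 probe were not used here. Lists with under 3 genes left under a setting gave no value. No paired analysis was possible because each transfection has 1 array. Signal over background limits the dim genes; how much of the larger counts without a level filter comes from noise and how much from more genes compared was not tested.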

Other observations

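The aminoacyl-tRNA synthetases were examined after the data were seen. They were picked as the compared genes whose symbols end in ARS1, a rule that leaves out synthetases with other symbols. Of these 16 genes, 6 were lower by 2-fold with the mimic, 9 with siPVT1-1 and 7 with siPVT1-2. Their medians were -0.54, -1.12 and -0.68, each below all 10000 random lists. The methionine enzyme gene MARS1 (-1.65, -1.52 and -1.58), the tryptophan enzyme gene WARS1 (-1.54, -1.75 and -1.53) and the cysteine enzyme gene CARS1 (-1.39, -1.89 and -1.8) were lower on all 3 arrays. The glutamine enzyme gene QARS1 stood at 0.59, 0.56 and 0.6, and the histidine enzyme gene HARS1 at -0.23, 0.42 and 0.08.

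Of the 21 literature miR-214 targets, 6 had their lowest level on the mimic array. The share of other genes that were lowest on that array was not set beside this count. Any gene is lowest on some array, so no conclusion about targeting is drawn from the count.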
